A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

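RNA was sequenced from rabbit (Oryctolagus cuniculus) tissue in 6 samples, 3 titled control and 3 titled test. The series title names perichondral tissue, the sheath of connective tissue around cartilage, while the sample labels give subcutaneous tissue as the source. Per the labels, total RNA was extracted with TRIzol, ribosomal RNA was removed with a Ribo-Zero kit, and libraries were made with a stranded total RNA kit. The labels do not state what the test samples received, nor whether the samples came from separate animals. The p-values therefore measure only the spread between these samples.

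The deposited table holds raw counts per gene for the 6 samples, per the file headers, and the values are whole numbers. A second block of 6 per-sample columns with counts normalized by the authors was not used here. The submitters' notes name cutadapt 1.9.3, HISAT2 and Cuffdiff without roles, and list rn6, a rat build, although the gene identifiers are rabbit Ensembl identifiers. The counting tool, its strand setting and the annotation release are not stated. The table holds protein-coding genes without genomic coordinates, so no positions are given. It contains no comparison between the groups made by the authors. Symbols were taken from the table itself, and 5067 of its 16367 genes have none. Values of genes in families with similar sequences (actins, myosin heavy chains, ribosomal proteins, ferritin, MHC genes, keratins) are uncertain, because reads can be shared between paralogs.

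Total counts per sample ranged from 17820537 to 23105606. Counts are sequencing reads without molecular identifiers, so intervals and floors computed from them cover counting error only. A group without a count was given a floor of 3 counts over the whole group, and folds against it are lower bounds. For groups with 1 to 3 counts, the ratio of depth-scaled counts is given with its exact 95% counting interval.

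The main comparison was the edgeR (4.0.16) quasi-likelihood test in R 4.3.3, two-sided, with TMM normalization and the filterByExpr filter (minimum count 10, minimum total count 15). It used all 6 libraries, with no block and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 12740 genes tested, and genes were called at an adjusted p under 0.05. Log2 fold changes are test over control. Their standard error is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Levels are edgeR's CPM, counts scaled to the normalized library size, with the standard deviation over the 3 libraries of a group. Group means of total counts were compared with a two-sided exact permutation test.

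Gene lists for cell types, matrix, signalling and metabolism were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and adjusted over the lists with at least 5 tested members. Of 36 lists, 33 had enough members, and 538 of the 916 list genes were tested. Camera was repeated with a correlation estimated from the data, and fry tested each list by itself. Members past the threshold were counted both ways, once adjusted over all genes tested and once adjusted over the list alone. The groups, the tests, the lists, most alternatives and the rule for named genes were set before the data were examined. The rule takes the 10 genes with a symbol that had the largest and the 10 that had the smallest log2 fold change among called genes whose groups do not overlap. It adds up to 4 members of each list with the smallest unadjusted p, and a fixed set of 10 matrix, regulator and control genes.

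Alternatives were DESeq2 size factors within edgeR, quantile normalization with limma-voom, no filter on low counts, a mean CPM of at least 5, the DESeq2 (1.42.0) Wald test, limma-voom, the replicate number as a block, a fold threshold of 2 and leaving out each library in turn. Chosen after the data were seen were thinning of every library to the smallest total, a restriction to genes with a genomic span, and a correction of each library for its trend with span, with and without the block. Spans came from RefSeq gene records of rabbit matched by gene number, and 8880 tested genes had one. The correction removed, in each library, a lowess curve (fraction 0.5) of each gene's deviation from its mean log2 CPM (pseudocount 0.5) against log2 span. Also chosen after the data were seen were 3 further lists, adjusted together, of which the mitochondrially encoded genes and the vacuolar proton pump are described. An over-representation test of KEGG pathways with 10 to 500 members was chosen then too. It was a one-sided hypergeometric test against the tested genes that have a pathway, run apart for genes that rose and genes that fell. Its p-values were adjusted over the 255 pathways in each direction. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

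The tests were checked on simulated counts with 200 changed genes among 12740. EdgeR recovered 54 of 100 genes changed by a log2 of 1 and 78 of 100 changed by a log2 of 2, with 9 false calls (6.38% of calls). The DESeq2 Wald test recovered 60 and 85 with 36 false calls, and limma-voom 53 and 75 with 11. Both groups were simulated with the same dispersion for each gene and without a trend with span. In the data the control libraries varied more and a trend with span was present, so these rates need not hold there. Camera found a planted list of 20 genes and called 0 of 30 unchanged lists. The simulated genes varied independently, so that check does not cover correlation between the members of a list. With a planted trend against span, the correction lowered false calls from 348 to 12 and recovered 173 changed genes instead of 178. With 800 random calls of random direction, the pathway test called 1 pathway over both directions together, each tested over 255 pathways.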

Results

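The 6 libraries fall into a control group and a test group of 3 each, as their titles give them, and the comparison of test with control is the only one the labels define. The labels do not state its purpose. Total counts were 22377952, 23105606 and 21923246 in control replicates 1 to 3 and 17820537, 20348301 and 21199562 in test replicates 1 to 3. Every control total was above every test total, which gives a two-sided exact permutation p of 0.1 (n = 3 per group), the smallest that 3 against 3 allows. Log2 expression correlated across genes, which are not independent replicates, at 0.966 to 0.967 among test libraries, 0.94 to 0.956 among control libraries and 0.924 to 0.936 between the groups. Control libraries also varied more, with a biological coefficient of variation of 31.5% against 19.7% among test libraries. The 13 mitochondrially encoded genes took 13.29%, 10.07% and 11.73% of the counts in control replicates 1 to 3 and 7.779%, 7.769% and 6.967% in test replicates 1 to 3.

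Compared with control tissue, the test tissue held more transcript of macrophage-derived giant cell genes, of muscle contraction genes and of the neutrophil S100 proteins. The giant cell, skeletal muscle and neutrophil lists passed camera with its preset correlation but not with one estimated from the data (adjusted p = 0.0719, 0.0606 and 0.126). ATP6V0D2 (ENSOCUG00000010247), a proton pump subunit of osteoclasts and fused macrophages, rose 5.82-fold, from 6.92 ± 2.2 to 40.2 ± 5.36 CPM (mean ± SD, n = 3 per group here and below, edgeR adjusted p = 0.000391). MYL1 (ENSOCUG00000014182), a fast muscle myosin light chain, rose 60.2-fold, from 0.295 ± 0.106 to 18 ± 2.37 CPM (edgeR adjusted p = 8.15e-05). S100A12 (ENSOCUG00000022646), a calcium-binding protein of neutrophils, rose 8.64-fold, from 2.43 ± 0.411 to 21.1 ± 2.07 CPM (edgeR adjusted p = 0.000182). COL3A1 (ENSOCUG00000014988), the fibrillar collagen of loose connective tissue, fell 2.02-fold, from 15500 ± 2940 to 7662 ± 605 CPM, and COL6A5 (ENSOCUG00000024036), a collagen VI chain, fell 13.5-fold, from 167.6 ± 124 to 12.4 ± 1.77 CPM (edgeR adjusted p = 0.00277 and 0.000993). Without control replicate 3, COL6A5 fell 7.75-fold.

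EdgeR called 1655 of 12740 genes, 872 higher and 783 lower in the test group, and 572 of them (345 higher, 227 lower) differed at least 2-fold. In 1645 of the called genes the 3 test values did not overlap the 3 control values, as held for 35% of all tested genes where chance gives 10%. The number of calls rested on the libraries kept. It was 710 without control replicate 3, 595 without test replicate 1, 471 without test replicate 2 and 446 without test replicate 3, against 2163 without control replicate 1 and 1925 without control replicate 2. With the replicate number as a block, 1681 genes were called (910 higher, 771 lower), 1464 of them in common with the unblocked calls in the same direction.

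**Figure D1:**
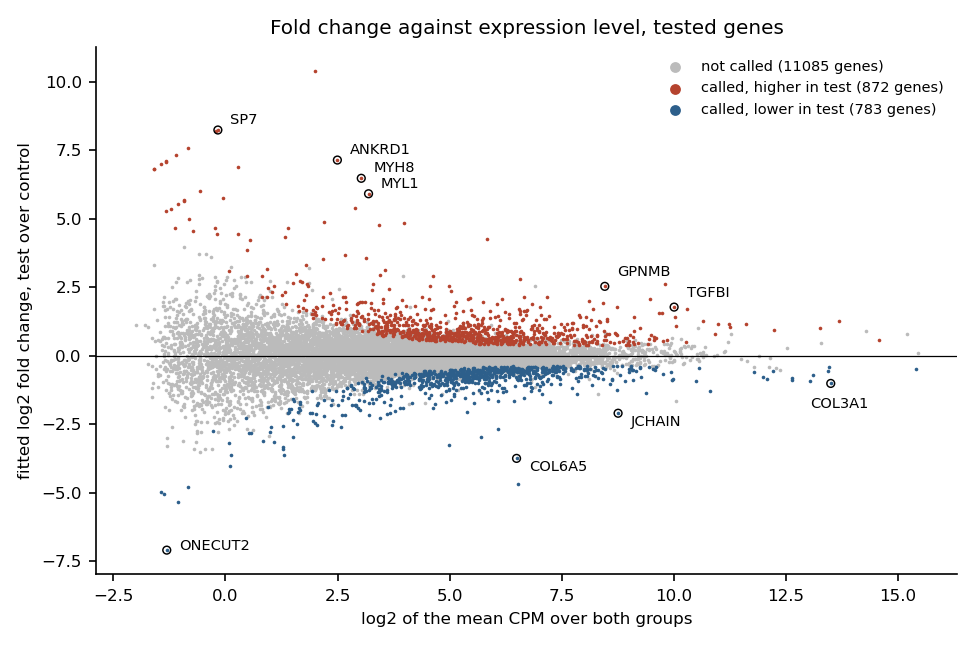
Log2 fold change of test over control against mean log2 CPM, 1 point per tested gene, with called genes coloured by direction and some named genes circled. The 872 genes called higher and the 783 called lower lie on both sides of a median of -0.0038.

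The 10 genes with the largest rises included 5 genes of striated muscle and the bone gene SP7. SP7, the osteoblast transcription factor, had 0 counts in the control group and 104 in the test group, at least 40.7-fold higher (edgeR adjusted p = 0.00664). ANKRD1, a stretch-responsive muscle protein, had 5 and 653 counts, a log2 fold change of 7.14 ± 0.73 (edgeR adjusted p = 0.000522). MYH7, the slow myosin heavy chain, had 1 count against 143, a ratio of 168 with a 95% counting interval of 29.7 to 6680 (edgeR adjusted p = 0.00368). The muscle genes CSRP3, CACNA1S and CKM had no control counts and were at least 25.4-fold, 21.1-fold and 16.8-fold higher. CYP24A1, the vitamin D hydroxylase, GIP, TCEAL7 and ZDHHC19 had none either and were at least 18.4-fold, 18-fold, 15.3-fold and 14.9-fold higher. The edgeR adjusted p of these 7 genes ran from 0.0137 to 0.0254. SP7, ANKRD1 and MYH7 stayed called without any single library. The control group had 0 counts of ANKRD1 without control replicate 2 and 0 of MYH7 without control replicate 1, which leaves them at least 174-fold and 36.2-fold higher. The bounds of the other 8 genes were from 9.62-fold to 26.3-fold without control replicate 1, where the same floor covers 2 libraries. The other 7 calls ended without any single test library (adjusted p from 0.0611 to 0.107), and all of these except CSRP3 also without control replicate 3 (0.0603 to 0.0756). With the replicate block the calls of CYP24A1, GIP, CKM, TCEAL7 and ZDHHC19 ended as well (adjusted p from 0.0518 to 0.0651). The block together with the span correction also ended those of CSRP3 and CACNA1S (0.0508 and 0.0621).

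Among the genes with the largest falls, COL6A5 alone stayed called without any single library, with a fall of 7.75-fold in place of 13.5-fold without control replicate 3. MYOC, a secreted protein of connective and ocular tissue, fell from 57.1 ± 37.7 to 5.95 ± 4.34 CPM, and GAPT from 4.48 ± 0.399 to 0.409 ± 0.479 CPM (edgeR adjusted p = 0.0143 and 0.0171). ONECUT2, a transcription factor, had 55 control counts and 0 test counts, at least 15.6-fold lower (edgeR adjusted p = 0.026). PCSK2, a prohormone convertase, had 49 counts against 1, a ratio of 41.7 (95% counting interval 7.15 to 1680), and ADAMTS18, a metalloproteinase, had 75 against 2, a ratio of 31.9 (8.54 to 268), with edgeR adjusted p of 0.0296 and 0.025. GALNT5, ZBTB20, LURAP1 and SCNN1B fell 16.2-fold, 12.5-fold, 12.3-fold and 10.2-fold (edgeR adjusted p = 0.0401, 0.0094, 0.0295 and 0.0392). Of the other 9 calls, 8 ended without control replicate 3 (adjusted p from 0.0559 to 0.203) and 7 without test replicate 1 (0.0554 to 0.132). Without test replicate 2, 8 ended (0.0538 to 0.132), and without test replicate 3, 7 ended (0.065 to 0.157). PCSK2, GALNT5 and LURAP1 were also not called without control replicate 2 (0.0637, 0.113 and 0.071), and PCSK2 not without control replicate 1 (0.0532). Without test replicate 2 the test group had 0 counts of PCSK2 and without test replicate 3 it had 0 of ADAMTS18, at least 9.17-fold and 13.7-fold lower. The bound of ONECUT2 was 10.1-fold without control replicate 3 and 10.3-fold and 10-fold without test replicates 2 and 3. Among the others the log2 fold change went from -4.02 to -3.29 and -6.01 for GALNT5 (without control replicate 2 and test replicate 2) and from -3.65 to -3.03 for ZBTB20 (control replicate 2). It went from -3.63 to -4.67 for LURAP1 (test replicate 1), from -3.35 to -2.32 and -4.85 for SCNN1B (control replicate 3 and test replicate 1), from -3.41 to -5.01 for GAPT (test replicate 3) and from -3.25 to -3.94 for MYOC (test replicate 2). Limma-voom did not call GALNT5, ZBTB20, LURAP1, SCNN1B or MYOC with its own (adjusted p from 0.0873 to 0.121) or quantile normalization (0.0715 to 0.11). The replicate block ended the calls of ONECUT2, PCSK2 and LURAP1 (0.0559, 0.0626 and 0.0621), no filter those of PCSK2 and ADAMTS18 (0.073 and 0.0527), and the span correction that of GALNT5 (0.051). The block together with the span correction also ended those of ADAMTS18 and SCNN1B (0.0707 and 0.0614).

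Of 33 gene lists, camera with its preset correlation called 18, with 12 higher and 6 lower in the test group. With a correlation estimated from the data 0 lists were called, where the smallest adjusted p was 0.0606, while fry called 11 in its directional form, 10 of them among the 18. Directional fry ended the calls of cell proliferation (adjusted p = 0.0577), of B and plasma cells, pericytes and interferon response (0.09 each), and of progenitors, adipocytes, hypertrophic cartilage and bone, and TGF-beta and BMP signalling (0.0747 each). Setting members absent from a group to their bound left every list median as it was.

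In the giant cell and lipid-laden macrophage list, 10 of 14 tested members rose and 0 fell, and the same numbers were found adjusted over the list alone. Its median log2 fold change was 1.31 (camera adjusted p = 2.08e-14, adjusted p = 0.0719 with an estimated correlation). MMP9, a gelatinase, rose from 46.3 ± 3.43 to 144.9 ± 23.6 CPM, CHIT1, a chitinase of lipid-laden macrophages, from 8.91 ± 0.727 to 37.4 ± 9.46 CPM, and GPNMB, a lysosomal glycoprotein, from 104 ± 11.4 to 600.3 ± 289 CPM (edgeR adjusted p = 0.000268, 0.000522 and 0.000781). The list of general macrophage and monocyte genes was not called (median 0.24, camera adjusted p = 0.0998), although it passed without control replicate 1 (adjusted p = 0.00214). Its median was 0.03 without control replicate 2 (0.204) and 0.13 without control replicate 3 (0.169), and turned to -0.03 after the span correction (0.604). In that list 6 of 21 members rose and 1 fell, and adjusted over the list alone 6 rose and 2 fell. ITGAX, the integrin CD11c, rose from 51.5 ± 8.93 to 100.2 ± 8.98 CPM, while CD163, the haemoglobin scavenger receptor, fell from 1287 ± 140 to 720.4 ± 85 CPM (edgeR adjusted p = 0.00378 and 0.00382).

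In the skeletal muscle list, 10 of 19 members rose and 0 fell, and adjusted over the list alone 12 rose. MYBPC1, the member with the most counts, had 6880 unscaled counts in the control group and 5268 in the test group. RYR1 had 289 and 335, and ENO3 had 310 and 349. The median log2 fold change was 2.77 (camera adjusted p = 5.44e-14, adjusted p = 0.0606 with an estimated correlation), and 4.29 without control replicate 1. ACTA1, skeletal actin, rose from 0.758 ± 0.818 to 20.6 ± 2.11 CPM, and NEB, the thin-filament protein nebulin, from 0.713 ± 0.367 to 8.32 ± 1.65 CPM (edgeR adjusted p = 0.00193 and 0.00223). Without control replicate 2 the log2 fold change of ACTA1 was 5.99 in place of 4.77. The values of ACTA1 and of the myosin heavy chains are uncertain because their paralogs can share reads. In the short list of myogenic progenitor genes, 1 of 5 members rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell. Its median was 2.77 (camera adjusted p = 0.00366, adjusted p = 0.187 with an estimated correlation). The tested members were MYH8, MEF2C, CHRNA1, CHRND and CHRNG. PAX7, PAX3, MYF5, MYF6, MYOD1, MYOG and MYMX had too few counts to be tested, so none of them contributes to this result. The member that rose was MYH8, the perinatal myosin heavy chain, from 0.177 ± 0.184 to 16.2 ± 2.36 CPM (edgeR adjusted p = 0.000293), with a log2 fold change of 6.48, and of 7.47 without control replicate 2. The member that fell was MEF2C, a transcription factor also expressed outside muscle (log2 fold change -0.60 ± 0.17, edgeR adjusted p = 0.0398). The MEF2C call ended without any single library except control replicate 2 (adjusted p from 0.0693 to 0.149) and after the span correction (0.169). The myogenic median was 4.46 without control replicate 2, and limma-voom with its own or quantile normalization ended the list's call (adjusted p = 0.238 and 0.24).

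**Figure D2:**
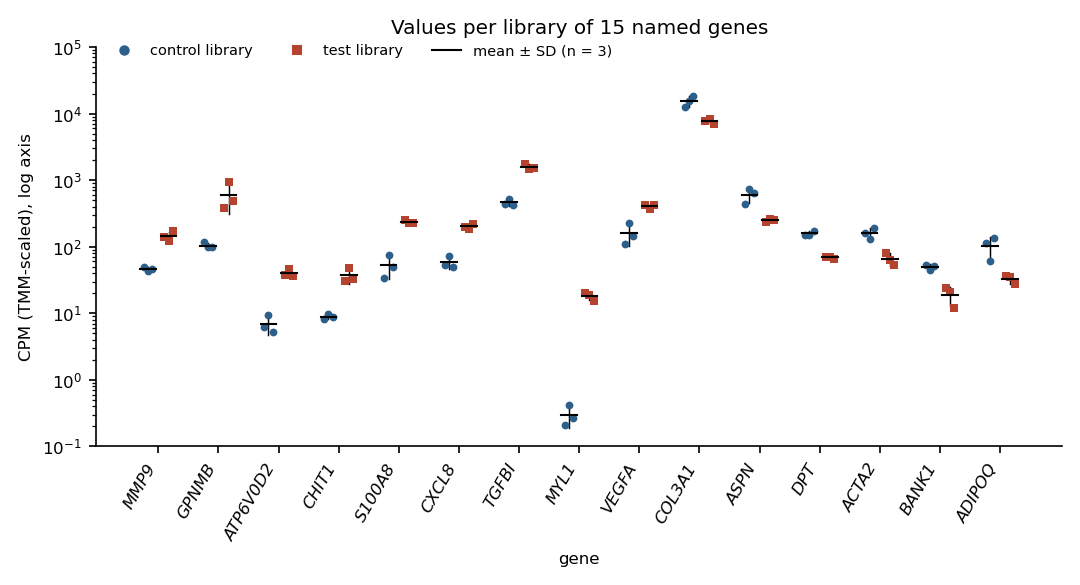
CPM on a log axis for 15 named genes, 1 point per library, with bars for the mean ± SD of each group (n = 3). MYL1 averages 0.295 CPM in the 3 control libraries and 18 CPM in the 3 test libraries.

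Neutrophil genes rose as a list, with 3 of 14 members called higher and 0 lower, and the same 3 adjusted over the list alone. Their median was 0.54 (camera adjusted p = 3.13e-05, adjusted p = 0.126 with an estimated correlation). The called members were S100A12, S100A8, which rose from 52.9 ± 19.9 to 233.8 ± 14 CPM, and S100A9, which rose from 37.5 ± 15.5 to 164 ± 15.1 CPM (edgeR adjusted p = 0.000182, 0.000641 and 0.000845). After the span correction the log2 fold change of S100A8 was 1.51 in place of 2.15. In the list of inflammatory cytokines and chemokines, 8 of 22 members rose and 2 fell, and adjusted over the list alone 8 rose and 6 fell. Its median was 0.06 (camera adjusted p = 0.00879, adjusted p = 0.187 with an estimated correlation). CXCL8, which attracts neutrophils, rose from 58.5 ± 12.5 to 202.1 ± 17.9 CPM, LIF from 3.94 ± 0.262 to 21 ± 6.89 CPM, IL1B from 27.4 ± 4.76 to 59 ± 3.89 CPM and IL1RN, the interleukin-1 receptor antagonist, from 130.5 ± 21 to 348.9 ± 35.1 CPM (edgeR adjusted p from 0.000293 to 0.00277). The cytokine list's call ended without test replicate 1 (adjusted p = 0.0533), with limma-voom (0.121), with quantile normalization (0.143, median 0.03) and after the span correction (0.669), where the median was -0.22. Its median was 0.14 without control replicate 1, -0.09 without control replicate 2, -0.01 without control replicate 3 and 0.003 without test replicate 3.

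Lists of B cell and interferon genes were lower with camera's preset correlation but not called with an estimated one (adjusted p = 0.381 and 0.443) or by directional fry (0.09 each). In the B and plasma cell list, 5 of 17 members fell and 0 rose, and adjusted over the list alone 7 fell. Its median was -1.18 (camera adjusted p = 5.08e-05, adjusted p = 0.381 with an estimated correlation) and -0.48 without control replicate 1. BANK1, a B cell scaffold protein, fell from 49.7 ± 4.74 to 18.7 ± 6.05 CPM, and JCHAIN, the joining chain of secreted antibodies, from 701.8 ± 412 to 163.3 ± 64.7 CPM (edgeR adjusted p = 0.00501 and 0.00896), the latter with an adjusted p of 0.0548 without test replicate 2 and a fall of 2.82-fold in place of 4.3-fold without control replicate 1. In the interferon response list, 8 of 21 members fell and 2 rose, and adjusted over the list alone 9 fell and 2 rose. Its median was -0.40 (camera adjusted p = 0.0226, adjusted p = 0.443 with an estimated correlation). PARP14 fell from 159.9 ± 18.6 to 93.8 ± 6.42 CPM, while ISG15, a ubiquitin-like interferon product, rose (log2 fold change 1.30 ± 0.28, edgeR adjusted p = 0.00475 and 0.0167). ISG15 was not called without test replicate 1 (0.0758), without test replicate 3 (0.082) or after the span correction (0.0889). The interferon list was not called without control replicate 3 (0.114), without test replicate 2 (0.0753) or among genes with a span alone (0.158), where its median was -0.14, and -0.27 after the span correction (0.0417). The T and NK cell list was not called (0 of 20 members, 0 adjusted over the list alone, median -0.52, camera adjusted p = 0.0716). It passed without control replicate 2 (0.0101), control replicate 3 (0.00343) or test replicate 2 (0.0267), after the span correction (0.0196) and with the DESeq2 Wald test (0.0462). Without control replicate 1 its median turned to 0.02 (0.996). Antigen presentation was not called either, with 1 of 12 members lower in both adjustments (median -0.29, camera adjusted p = 0.0601). It passed without control replicate 2 (8.56e-05) or test replicate 1 (0.0193), after the span correction (0.0322), with no filter (0.0361), with the block (0.026) and with the DESeq2 Wald test (0.028). Its median was -0.06 without control replicate 1 (0.456), -0.55 without control replicate 2 and -0.18 without test replicate 3, and -0.15 with quantile normalization (0.195).

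Matrix genes went both ways. In the fibrillar and fibrosis matrix list, 6 of 26 members rose and 4 fell, and adjusted over the list alone 7 rose and 4 fell. The list was not called (median 0.13, camera adjusted p = 0.102) but passed without control replicate 2 (0.000943) and with the block (0.0377). Its median turned to -0.09 without control replicate 1 (0.996) and was 0.39 without control replicate 2 and 0.08 without test replicate 3 and with quantile normalization. LOXL1, which cross-links elastin, rose from 48.7 ± 5.44 to 140.8 ± 10.3 CPM, TNC, the matricellular protein tenascin C, from 574.9 ± 212 to 1519 ± 83.3 CPM, and BGN, a small proteoglycan, from 1920 ± 525 to 4299 ± 530 CPM (edgeR adjusted p = 0.00026, 0.00403 and 0.00446). COL1A1 fell from 5107 ± 1230 to 2990 ± 390 CPM (edgeR adjusted p = 0.0177), a call that ended without control replicate 3 (0.061) and without test replicate 1, 2 or 3 (0.0567, 0.0746 and 0.0898). In the matrix degradation list, 7 of 22 members rose and 3 fell, and adjusted over the list alone 7 rose and 4 fell. Its median was 0.56 (0.32 without control replicate 1, camera adjusted p = 0.00274, adjusted p = 0.245 with an estimated correlation). For the members with a span it went from 0.59 to 0.31 after the span correction (0.0156). TIMP1, a metalloproteinase inhibitor, rose from 417.1 ± 65.3 to 1213 ± 235 CPM, CTSB, a lysosomal protease, from 1586 ± 231 to 3292 ± 148 CPM, and PLAUR, the urokinase receptor, from 30.7 ± 5.34 to 69 ± 2.17 CPM (edgeR adjusted p = 0.000714, 0.00108 and 0.00177).

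The perichondrial and mesenchymal progenitor list fell, with 4 of 12 members lower and 1 higher, and adjusted over the list alone 5 lower and 1 higher. Its median was -0.40 (camera adjusted p = 0.0322, adjusted p = 0.381 with an estimated correlation). DPT, the collagen-binding protein dermatopontin, fell from 159 ± 13.5 to 69.5 ± 2.67 CPM, ASPN, a small proteoglycan, from 601.7 ± 151 to 250.5 ± 13.6 CPM, and POSTN, a matricellular protein of periosteum, from 2538 ± 813 to 1027 ± 206 CPM (edgeR adjusted p = 0.000404, 0.00224 and 0.00732). CTSK, the collagen-degrading protease of osteoclasts, was the member that rose, from 3318 ± 263 to 6335 ± 197 CPM (edgeR adjusted p = 0.000834). The list's call ended without control replicate 2 (0.0638), control replicate 3 (0.109) or test replicate 1 (0.0533), and with quantile normalization (0.143), no filter (0.055), limma-voom (0.121), genes with a span alone (0.0966) and the span correction (0.0826). The median shrank to -0.08 with no filter, to -0.07 among genes with a span and to -0.13 after the correction (-0.10 with the block). PRRX1, a mesenchymal transcription factor, had a log2 fold change of -0.07 ± 0.29 and was not called (edgeR adjusted p = 0.901).

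Cartilage matrix genes were not called as a list (median 0.04, camera adjusted p = 0.146), except without control replicate 2 (0.00439). The median was -0.05 without control replicate 1 (0.996), 0.23 without control replicate 2 and 0.15 without control replicate 3, and 0.23, 0.11 and 0.09 without test replicates 1 to 3. It ran from 0.02 with quantile normalization to 0.33 with the block after the span correction. Of 15 members, 2 rose and 0 fell, and adjusted over the list alone 4 rose and 1 fell. MATN4, a matrilin, rose from 1.38 ± 1.4 to 16.2 ± 8.51 CPM (edgeR adjusted p = 0.00802), with a log2 fold change of 3.56, and of 4.80 without control replicate 2. COL2A1, the main cartilage collagen, was at 973 ± 488 and 997.7 ± 295 CPM (edgeR adjusted p = 0.96). ACAN, the cartilage proteoglycan aggrecan, was at 996.3 ± 510 and 1980 ± 317 CPM and missed the threshold (edgeR adjusted p = 0.0554). ACAN passed it with the block (0.0133), with limma-voom (0.0313), with quantile normalization (0.0391), with no filter (0.0275), among genes with a span (0.0441), after the span correction (0.0385) and without control replicate 1 (0.036) or control replicate 2 (0.00158). The list of chondrogenic regulators had 1 of 11 members higher in both adjustments (median 0.26, camera adjusted p = 0.132, and 0.00324 without control replicate 2). Its median was 0.15 without control replicate 1, 0.64 without control replicate 2 and 0.42 without test replicate 1, and 0.43 after the span correction. SOX9, its main transcription factor, had a log2 fold change of 0.26 ± 0.29 (edgeR adjusted p = 0.592). In the hypertrophic cartilage and bone list, 4 of 12 members rose and 0 fell, and 5 rose adjusted over the list alone. Its median was 0.39 (camera adjusted p = 0.000368, adjusted p = 0.381 with an estimated correlation). It moved to 0.21 without control replicate 1 and 1.40 without control replicate 2, and to 1.11 with the block, 1.07 with limma-voom, 0.94 with quantile normalization, 1.06 with no filter and 0.84 with the block after the span correction. Besides SP7, the bone matrix phosphoprotein SPP1 rose from 190.2 ± 106 to 658.5 ± 3.92 CPM (edgeR adjusted p = 0.013, and 0.0552 and 0.0517 without test replicate 2 or 3). RUNX2, an osteoblast transcription factor, had a log2 fold change of 0.31 ± 0.23 (edgeR adjusted p = 0.41). COL10A1, ACTB and GAPDH were not found by symbol and are not analysed here.

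TGF-beta and BMP signalling genes rose, with 7 of 24 members higher and 1 lower, and adjusted over the list alone 10 higher and 2 lower. Their median was 0.46 (0.29 without control replicate 1, camera adjusted p = 0.000385, adjusted p = 0.381 with an estimated correlation). TGFBI, a TGF-beta-induced matrix protein, rose from 465.9 ± 52.4 to 1591 ± 159 CPM, and the BMP target genes ID3 and ID1 from 21.9 ± 3.97 to 84.5 ± 19.5 CPM and from 29 ± 6.81 to 90.4 ± 19.1 CPM (edgeR adjusted p = 0.000182, 0.000522 and 0.00127). The log2 fold change of ID1 was 1.64, and 1.01 after the span correction. WNT signalling was not called, with 2 of 20 members higher and 2 lower, and adjusted over the list alone 5 higher and 2 lower. Its median was 0.38 (camera adjusted p = 0.157), and 0.22 without test replicate 3 (0.382). DKK3, a member of the dickkopf family, rose from 11.5 ± 4.75 to 36.2 ± 7.21 CPM (edgeR adjusted p = 0.00643).

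Glycolysis and hypoxia genes rose, with 9 of 22 members higher and 1 lower, and adjusted over the list alone 11 higher and 1 lower. Their median was 0.42 (camera adjusted p = 9.25e-06, adjusted p = 0.245 with an estimated correlation). ANGPTL4, a hypoxia-induced lipase inhibitor, rose from 16.7 ± 4.57 to 70.9 ± 18.4 CPM, CA9, a carbonic anhydrase, from 7.43 ± 1.6 to 22.2 ± 1.4 CPM, and PKM, pyruvate kinase, from 419.9 ± 7.55 to 666.6 ± 3.41 CPM (edgeR adjusted p = 0.000913, 0.00207 and 0.0033). VEGFA, the angiogenic growth factor, rose from 162.9 ± 60.6 to 403.6 ± 32.8 CPM (edgeR adjusted p = 0.00588). In the heat shock and immediate early list, 9 of 22 members rose and 0 fell, and 11 rose adjusted over the list alone. Its median was 0.43 (camera adjusted p = 9.25e-06, adjusted p = 0.16 with an estimated correlation). IER3 rose from 137.6 ± 14.3 to 452.3 ± 37.9 CPM (edgeR adjusted p = 0.000182), with a log2 fold change of 1.72, and of 1.12 after the span correction. In the nuclear-encoded oxidative phosphorylation list, 7 of 19 members rose and 0 fell, and 9 rose adjusted over the list alone. Its median was 0.36 (camera adjusted p = 0.00162, adjusted p = 0.381 with an estimated correlation). NDUFA2, a complex I subunit, rose from 18 ± 1.2 to 32.6 ± 0.552 CPM (edgeR adjusted p = 0.00762). Of 11 ribosomal protein genes, 4 rose and 0 fell, and 6 rose adjusted over the list alone. Their median was 0.42 (camera adjusted p = 0.0065, adjusted p = 0.381 with an estimated correlation). RPL32 rose with a log2 fold change of 0.57 ± 0.12 (edgeR adjusted p = 0.016), although not without control replicate 3 (0.0536) or test replicate 1, 2 or 3 (0.0786, 0.0719 and 0.0636), and its processed copies can share reads.

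Heat shock and ribosomal protein genes moved with a trend by genomic span. Among 8880 genes with a span, the log2 fold change fell with span (Spearman's rho -0.335 across genes, which are not independent replicates). In the quintile with spans of 0.264 to 11.1 kb, 294 genes were higher and 29 lower, and in the quintile of 111 to 2260 kb, 44 were higher and 205 lower. After each library was corrected for its trend, the median of the members with a span went from 0.45 to 0.12 for heat shock and immediate early genes (camera adjusted p = 0.151) and from 0.28 to -0.17 for ribosomal proteins (0.199), which turned their direction. For oxidative phosphorylation it went from 0.25 to 0.20, and the list was not called either (0.149). NDUFA2 then had a log2 fold change of 0.34 and was not called (adjusted p = 0.176), and RPL32 one of -0.21 (0.397). Already among genes with a span alone, the ribosomal protein list was not called (0.0757).

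**Figure D3:**
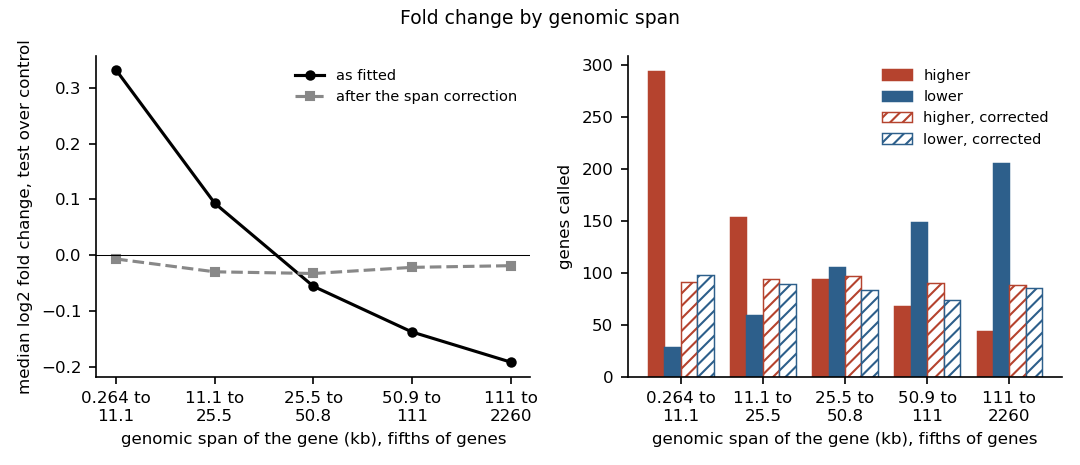
Median log2 fold change of test over control (left) and number of called genes (right) in the quintiles of genomic span in kb, before and after the correction of each library, for the 8880 tested genes with a span. The median falls from 0.33 in the shortest quintile to -0.19 in the longest before the correction.

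Cell proliferation genes fell as a list, with 4 of 27 members lower and 0 higher, and 11 lower adjusted over the list alone. Their median was -0.52 (camera adjusted p = 4.54e-05, adjusted p = 0.381 with an estimated correlation). KIF11, a motor protein of the mitotic spindle, fell from 33.4 ± 4.05 to 15.9 ± 3.76 CPM (edgeR adjusted p = 0.00983, and 0.0525 and 0.0609 without test replicate 1 or 3). In the pericyte and smooth muscle list, 3 of 13 members fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose. Its median was -0.84 (camera adjusted p = 0.00477, adjusted p = 0.381 with an estimated correlation, and 0.0511 without control replicate 3). RGS5, a pericyte marker, fell from 82.3 ± 6.81 to 41.4 ± 5.2 CPM and ACTA2, smooth muscle actin, from 160.8 ± 31.6 to 65.2 ± 14 CPM (edgeR adjusted p = 0.00234 and 0.00277). The member that rose was DES, desmin, an intermediate filament also of skeletal muscle, from 2.53 ± 0.846 to 7.84 ± 0.659 CPM (edgeR adjusted p = 0.0157, and 0.0586, 0.0761 and 0.0646 without test replicate 1, 2 or 3). In the adipocyte list, 3 of 9 members fell and 1 rose, and adjusted over the list alone 4 fell and 1 rose. Its median was -0.54 (camera adjusted p = 0.048, adjusted p = 0.381 with an estimated correlation). ADIPOQ, the fat hormone adiponectin, fell from 103.1 ± 38.3 to 32.6 ± 4.59 CPM (edgeR adjusted p = 0.0038). The adipocyte call ended without control replicate 3 (0.137) or test replicate 1 (0.0921), and with limma-voom (0.0989), quantile normalization (0.118), no filter (0.0763), a mean CPM of at least 5 (0.0543), genes with a span alone (0.0757) and the span correction (0.0529).

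**Figure D4:**
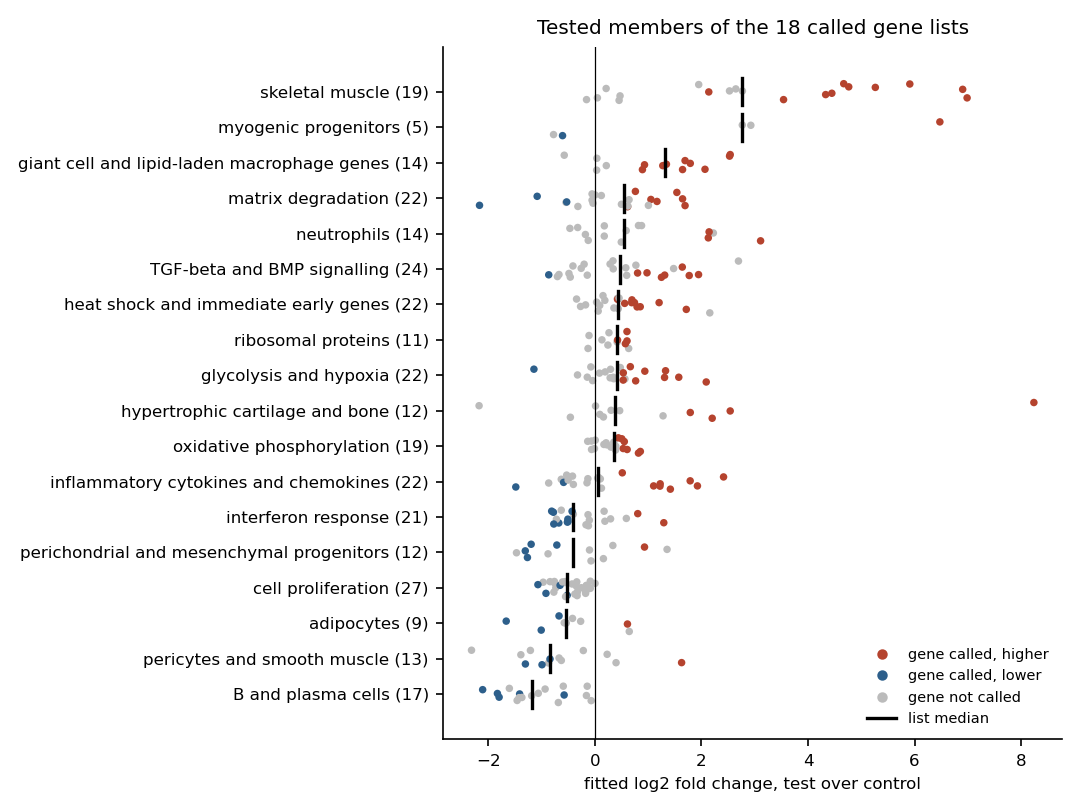
Log2 fold changes of the tested members of the 18 called lists, 1 point per gene, with the list median as a bar and called genes marked. Medians run from 2.77 for skeletal muscle to -1.18 for B and plasma cells.

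The remaining lists were not called. They were the unfolded protein response (5 of 20 higher, 0 lower, median 0.19, camera adjusted p = 0.0998) and endothelium and angiogenesis (1 of 23 higher, 2 lower, median -0.23, adjusted p = 0.146). Both passed without control replicate 2 (0.0269 and 0.0106). Without control replicate 1 their medians were 0.12 and -0.05, and that of endothelium was -0.41 and -0.14 without control replicates 2 and 3. After the span correction the median of the unfolded protein response was 0.02. Antioxidant response (2 of 15 higher, 1 lower, median 0.22, camera adjusted p = 0.253) and housekeeping genes (1 of 8 higher, 1 lower, median 0.16, adjusted p = 0.449) did not pass. Epidermis and hair follicle genes (0 of 9 called, median -0.92, camera adjusted p = 0.531), complement and coagulation (2 of 15 higher, 1 lower, median 0.24, adjusted p = 0.586) and Schwann cells and nerve (1 of 8 higher, 0 lower, median -0.26, adjusted p = 0.636) were not called either. Apoptosis and senescence genes (2 of 15 higher, 2 lower, adjusted p = 0.634) had a median of 0.02, while their mean was -0.001 and camera's direction was down. That median ran from -0.18 to 0.06 without 1 library and from -0.19 to 0.10 over the other settings. Directional fry called complement and coagulation (adjusted p = 0.0453). The median of complement and coagulation turned to -0.003 without control replicate 2 and was 0.13 without control replicate 3. For the antioxidant response it was 0.06 and 0.09 without control replicate 2 or test replicate 1, for housekeeping genes 0.04 without control replicate 2, and for epidermis between -0.28 and -0.47 without 1 control library or test replicate 2. The span correction turned the medians of complement (-0.09), antioxidant response (-0.03) and housekeeping genes (-0.14), and no filter turned that of epidermis (0.49). In all of these lists the numbers adjusted over the list alone were the same. Single genes of these lists still differed. TXN, thioredoxin, rose from 159.3 ± 8.9 to 347.1 ± 12.6 CPM, its inhibitor TXNIP fell from 140.6 ± 18.4 to 70.6 ± 5.13 CPM, and TFPI, the tissue factor pathway inhibitor, fell from 85.8 ± 8.56 to 35.7 ± 6.8 CPM (edgeR adjusted p = 0.000391, 0.00186 and 0.00133). Lists of mast cells, melanocytes and erythroid cells had only 4, 4 and 3 tested members and were not tested as lists, and 1 member fell, 1 rose and 1 fell in them. The member that rose was MLANA, a melanocyte protein, from 25 ± 4.41 to 59 ± 9.79 CPM (edgeR adjusted p = 0.00302). The members that fell were FCER1A (log2 fold change -1.24, edgeR adjusted p = 0.0286, and 0.125 without test replicate 2 or 3) and GATA1 (-2.79, 0.0493). Without test replicate 1 the log2 fold change of GATA1 was -3.93. The GATA1 call ended without control replicate 3 (0.197), test replicate 2 (0.162) or test replicate 3 (0.136), and with limma-voom (0.073), quantile normalization (0.0662), the block (0.0671), thinning (0.057) and genes with a span alone (0.0511).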

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

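Of the tests in this part, those chosen only after the result was seen are the thinning to equal depth, the restriction to genes with a span, the span correction with or without the block, and the pathway test. The 1655 calls (872 higher, 783 lower) were between 1649 and 1696 with DESeq2 size factors, quantile normalization, no filter, a mean CPM of at least 5, limma-voom, the replicate block (1681) and thinning, and 2316 by the DESeq2 Wald test, which made more false calls in simulation. Leaving out 1 library gave 446 to 2163 calls (245 to 1185 higher, 201 to 978 lower). The calls were fewer without control replicate 3 or a test library and more without control replicate 1 or 2 (2163 and 1925). Control replicates 1 and 2 lay far apart, at 44.9 and -53.9 on the second principal component of log2 CPM. That component held 22% of the variance, with control replicate 3 at 10.7 and the test libraries between -7.59 and 4.80. Whether this spread is the cause was not tested. A fold threshold of 2 left 572 (345 higher, 227 lower). The span correction gave 889 (460 higher, 429 lower), and 917 with the block (486 higher, 431 lower), among 8880 genes that gave 1200 uncorrected, which shows part of the cause in the smaller number of genes.

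Of 33 lists, camera called 18 with its preset correlation and 0 with an estimated one, and fry called 11 in its directional form, 10 of them among the 18, and 29 in its mixed form. Leaving out 1 library gave 15 to 24 called lists, and 13 of the 18 were called in all of these fits. Ribosomal proteins reversed to a median of -0.17 after the span correction and to -0.16 with the block, and RPL32 to -0.21 (± 0.15, adjusted p = 0.397) and -0.20 (adjusted p = 0.444), where the trend removed is the cause by construction. Of 125 called named genes, 61 were called in all 6 fits without 1 library, and the cause was not tested for the others. Over-represented pathways numbered 7 among genes that rose (2 to 12 over the alternatives) and 1 among genes that fell (0 to 15). Pseudocounts for normalized values were not run because the table holds counts, and no comparison by the authors is in it. Low counts limit the folds of genes absent from a group, which are bounds.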

Other observations

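Tests chosen only after the result was seen are the pathway test, the added lists, the thinning, the span correction, the comparison of the library slopes, and all tests of the muscle and giant cell patterns. Genes named in this part outside the rule were chosen after their values were seen. The pathway test takes genes as independent draws, so its p-values do not measure the spread between libraries. Genes of the KEGG lysosome pathway were over-represented among the genes that rose, with 23 of 81 where 6.71 were expected (one-sided hypergeometric adjusted p = 1.6e-05), and with 16 of 78 after the span correction (adjusted p = 0.00272). Without test replicate 1, 2 or 3 the pathway had 15, 9 and 11 called genes (adjusted p = 9.99e-06, 0.0226 and 0.000794). GLB1, the lysosomal beta-galactosidase, rose from 129.3 ± 3.65 to 294.5 ± 26.8 CPM, and SLC11A1, a metal transporter of phagosomes, from 0.919 ± 0.525 to 11.8 ± 2.97 CPM (edgeR adjusted p = 0.000394 and 0.00108). In an added list of the vacuolar proton pump, 3 of 13 members rose, and adjusted over the list alone 6 rose and 1 fell (median 0.22, camera adjusted p = 0.000891, adjusted p = 0.0911 with an estimated correlation). The oxidative phosphorylation pathway had 18 of 58 genes called higher where 4.80 were expected (adjusted p = 3.6e-05), 16 of 43 among genes with a span (expected 3.91, adjusted p = 5.07e-05) and 9 of 43 after the span correction (expected 2.60, adjusted p = 0.0653). Members of the vacuolar proton pump list (ATP6V0D2, ATP6V0B and ATP6V0E1) were among the called genes of this pathway. Of 4 disease pathways that share 13 to 15 of its called genes, those of Alzheimer's, Huntington's and Parkinson's disease did not pass with the replicate block (0.0585, 0.304 and 0.396), nor without control replicate 2 or 3 or any test replicate. Huntington's and Parkinson's also did not pass without control replicate 1 (0.114 and 0.0899), nor Parkinson's with the DESeq2 Wald test (0.0681). The fourth, non-alcoholic fatty liver disease, did not pass without test replicate 1 or 3 (0.054 and 0.119). After the span correction it had 9 of 69 genes called (0.38) in place of 19 of 69, and the other 3 did not pass either (0.706, 1 and 1). Of the oxidative phosphorylation pathway, 10, 10, 8 and 9 genes were called without control replicate 3 and without test replicates 1 to 3. The rheumatoid arthritis pathway had 13 of 46 before (adjusted p = 0.00348) and 10 of 46 after (0.0396). Among the genes that fell, platelet activation was over-represented before the span correction only (18 of 77, expected 6.28, adjusted p = 0.00744), and not without control replicate 3 (0.249), test replicate 1 (0.193) or test replicate 2 (0.37), and it had 8 called genes without test replicate 3. That pathway holds COL3A1 and PPP1R12A, a myosin phosphatase subunit (log2 fold change -1.19 ± 0.14, edgeR adjusted p = 0.000913).

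Of the 13 mitochondrially encoded genes, 11 fell, and 13 adjusted over the list alone (median -0.70, camera adjusted p = 4.3e-13, adjusted p = 0.0911 with an estimated correlation). COX1, a subunit of the terminal oxidase, fell from 50190 ± 3390 to 35850 ± 2100 CPM (edgeR adjusted p = 0.0161), a call that ended without control replicate 3 (0.0645) or test replicate 1, 2 or 3 (0.0694, 0.0738 and 0.0834). The added lists were chosen on these samples, so their counts are not independent evidence of their direction.

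With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split, counted as 1 of the 10, gave 1655 called genes, and the highest other split gave 1. With every library thinned to the smallest total, 1650 genes were called.

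Long genes were lower and short genes higher in the test libraries, and the trend of each library's counts with span had slopes of 0.00763, 0.106 and 0.0405 in control replicates 1 to 3 and of -0.0574, -0.0525 and -0.0443 in test replicates 1 to 3. Of the 1200 calls among genes with a span, 718 or 59.8% (95% exact binomial interval 57 to 62.6) stayed called in the same direction after the correction. That argues against the trend with genomic span as the whole cause of these calls. The binomial interval takes genes as independent draws, so it does not measure the spread between libraries. Span is the length of a gene on the genome, and a trend with transcript length was not tested. Spans were known for 93.2% of tested genes with a symbol but for 69.7% of all tested genes, so that this check is void for the unnamed genes. RNA quality and a difference in the tissue cannot be told apart as the source of the trend, because the gap between the groups was 0.527 times the widest range within a group and the slopes follow the groups.

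In the skeletal muscle list 10 of 19 genes rose, and the trend with span is argued against as the whole cause, since 7 of the 7 with a span stayed called higher after the span correction. Depth is argued against too. The unscaled test counts of the 19 genes were a median of 5.67 times the control counts (95% bootstrap interval 3.17 to 17.3, floor of 3 counts over a group). The group totals had a ratio of 0.881. That median is taken over genes, which are not independent replicates, so its interval does not measure the spread between libraries. This depth test replaced one by thinning (9 of 10 stayed called). Mature muscle fibres taken along with the tissue would bring their abundant transcripts CKM and MB, but over the 3 test libraries these had 43 and 42 counts against 939 of the perinatal MYH8, a ratio of 0.0905 (95% counting interval 0.0716 to 0.113), where the control group had 0, 0 and 12, and of other mature fibre genes CASQ1 and PYGM had 151 and 273 counts in the control group and 150 and 240 in the test group, but ATP2A1, MYH1, MYH4 and MYOZ1 had 70, 13, 0 and 1 in the control group and 366, 293, 35 and 46 in the test group. This test does not decide the matter, since it replaced an earlier one on the ratio of MYH8 to MYH1 and MYH4 (2.86), its bound of 1 rests on textbook knowledge because no muscle library is in the series, and myosin paralogs share reads. MYOG, a factor of muscle differentiation, had 0 counts in the control group and 35 in the test group. PAX7, MYF5, MYF6, MYOD1 and MYMX had 0 in the control group and 3, 6, 7, 2 and 1 in the test group. PAX3 had 0 in both. CHRND and CHRNG had 10 and 10 control counts against 59 and 69, while CHRNA1 had 72 against 36 and MEF2C 3241 against 1805. Mature fibres taken along and a hypothesis of immature or regenerating muscle cells, which may be present in the test pieces, cannot be told apart.

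Giant cell genes rose more than general macrophage genes. The medians of the lists were 1.31 over 14 genes and 0.24 over 21 genes (0.03 and 0.13 without control replicates 2 and 3), a difference of 1.073 (95% bootstrap interval 0.136 to 1.74, permutation p = 0.00057). The test was chosen after the giant cell list had shown the smallest camera p of the 33 lists, and genes rather than libraries were resampled. The difference therefore cannot decide whether more macrophages of the same kind are the whole cause. After the span correction 10 of the 10 called giant cell genes were still called higher, and the medians were 1.07 and -0.03, which argues against the trend with span. Another candidate explanation that stays open and was not tested is a change of macrophage state or fusion in the test tissue. The labels do not state the treatment, and cells were not counted. Genes are not independent replicates in this test, and neutrophil and muscle genes moved with the same groups.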
